A study of Mus musculus with 2 samples.

How the data were processed

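Total RNA of embryonic facial prominence from B6NCrl mouse embryos of embryonic day 15.5 was sequenced in 2 libraries, which the labels gave as biological replicates 1 and 2 of the same tissue, age and strain, with the same donor label. Per the labels, replicate 1 pooled 78 embryos and replicate 2 pooled 62, RNA was extracted with a mirVana kit, 10 ng of RNA over 200 nucleotides long entered each library, and a spike-in set was named. The labels call the assay total RNA-seq and also link the manual of a kit for very small RNA amounts, so whether polyadenylated RNA was favoured is not settled by the sources used here.

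The authors aligned reads to the mouse transcriptome of assembly mm10 with annotation M4 and quantified each library by itself, per the text deposited with the samples. The aligner, the quantification program, their versions and the strand setting are not given in the sources used here. Each table held 69691 rows, of which 43346 carried Ensembl gene identifiers, 97 were spike-in sequences and 26248 carried a bare number. Per the file headers, the authors gave an expected count, TPM and FPKM for each gene and each transcript, with no scaling between libraries. Values of TPM as deposited summed over genes, spike-ins and numbered sequences alike, so the spike-in share lowers the TPM of genes. The authors' posterior mean TPM was used as an alternative. The percent of a gene's transcripts taken by each transcript was deposited beside these values. Deposited credibility bounds of TPM, which are in TPM but sum to no fixed total and were recorded here as a score, were used for the gene pairs, and their level is not printed in the tables. Effective length was the length minus 99 for sequences of 100 nucleotides or more, as tested on the values.

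Expected counts summed to 37128010 in replicate 1 and 38543623 in replicate 2. A single read on a transcript of 1 kb made 0.0406 TPM and 0.0389 TPM, and spike-ins took 2.91% and 4.59% of the counts. Genes were named by GENCODE M21 (GRCm38), which held 42462 of the 43346 identifiers, 23106 of them at the same version, and the 884 others took 0.200% and 0.207% of TPM. Of the numbered sequences 26185 were under 100 nucleotides and had no effective length. All numbered sequences were left out of every comparison, as were the spike-ins except for scaling and for their own ratio.

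Choices of gene lists, gene pairs, isoform genes, tests and alternatives were made before the data were examined, from the labels alone. Fixed were 48 marker and pathway lists, the ribosomal protein and replication-dependent histone genes, 24 gene pairs and 22 isoform genes. The lists were cartilage, bone, osteoclast, skeletal muscle, tendon, tooth regulators, enamel and dentin matrix, basal and simple epithelium, suprabasal and cornified epidermis, hair follicle placode, cranial mesenchyme transcription factors, arch patterning, Hox, palate, pan-neuronal, sensory neuron, forebrain, olfactory epithelium, lens and retina, Schwann and glia, melanocyte, endothelium, pericyte and smooth muscle, erythroid, macrophage, mast cell, lymphocyte, adipocyte, salivary gland, pituitary, liver, heart, lung, gut, kidney and pancreas, cell cycle, immediate early and heat shock, hypoxia, imprinted, sex chromosome, mitochondrial messenger RNA, non-polyadenylated RNA, nuclear long noncoding RNA, and the Hedgehog, BMP, FGF, Wnt and retinoic acid pathways and housekeeping genes.

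Named genes followed a rule written at the same time. It took the 3 members of each list with the highest mean TPM and the 20 most abundant nuclear coding genes. It took the 10 coding genes with the largest positive and the 10 with the largest negative ratio between replicates among those with 100 or more counts in the library with more counts. It took every member of the sex chromosome, arch patterning, enamel and dentin, Hedgehog and non-polyadenylated lists, the Hox genes at 1 TPM or more, and the fixed pairs and isoform genes. Where room was short, later names of a list were left out, never chosen by their value. A few genes that the rule names are not reported here.

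A gene was detected at 1 TPM or more, and levels were averaged as log2(TPM + 1). Ratios between replicates used expected counts rounded to whole numbers, TMM factors of 0.989 and 1.01 from edgeR 4.0.16 in R 4.3.3, and a prior count of 2. They were computed for genes with 10 or more counts in both libraries. The common dispersion came from edgeR with both libraries as 1 group and is given as the biological coefficient of variation. DESeq2 1.42.0 gave other size factors and dispersions. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and blastn 2.17.0 matched pseudogenes to coding transcripts.

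The level of a list was its mean log2(TPM + 1) over members and libraries, set against 10000 random lists of the same size drawn from coding genes at 1 TPM or more in either library, and its median TPM was given beside it. For the shift between replicates, the median log2 ratio was set against 10000 random lists in which each member was replaced by 1 of the 100 coding genes nearest in expression. A list was called apart outside the central 95% of these, if at least 3 members had 10 or more counts in both libraries. For single genes a change of 2-fold or more was counted among genes with 100 or more counts in the library with more counts. Gene pairs used TPM with a pseudocount of 0.1, and were called when the credibility intervals were apart in both libraries with the same direction. Isoform shares were computed from transcript TPM in genes at 10 TPM or more. Exact conditional binomial intervals at 95% cover counting error of single genes, and a gene with 0 counts was set to a floor of 3 counts per library. No test with a p-value was made, because 2 replicates of 1 group give no contrast.

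The procedure was tested on simulated data. With a simulated coefficient of variation of 15%, 14.9% was recovered, or 16.9% with changed genes included. Of 50 genes changed at each size, the 2-fold count found 8 at 1.5-fold, 23 at 2-fold, 49 at 3-fold and 50 at 4-fold, while 43 of 14105 unchanged genes passed. A list of 20 genes shifted by 1.3-fold was recovered at 1.35-fold and lay apart, and 7 of 200 unshifted lists (3.5%) lay apart.

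Alternatives were DESeq2 size factors, library totals and spike-in totals in place of TMM, other minimum counts, pseudocounts and prior counts, FPKM or posterior mean TPM in place of TPM, ratios of TPM, coding genes only, random lists matched on length or drawn from all coding genes, and each replicate left out. A count without pseudogenes, further gene lists, and for these lists a minimum of 10 counts in both libraries, were added after seeing the data. For these lists, and for the pseudogenes, the minimum of 10 or 100 counts applied to the library with more counts, since some members had few counts in the other library, and shuffled groups of pseudogenes (10000 draws) gave the random range. Sequence variants and alternative polyadenylation were not analysed here.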

Results

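The data were 2 total RNA-seq libraries of embryonic facial prominence, the tissue that forms the face and jaws, from B6NCrl mouse embryos of embryonic day 15.5. The labels gave them as biological replicates of 1 group, each made from 10 ng of RNA over 200 nucleotides long. Replicate 1 was a pool of 78 embryos and replicate 2 a pool of 62 embryos, both of mixed sex. Expected counts summed to 37128010 in replicate 1 and 38543623 in replicate 2, of which 36048494 and 36774513 lay on mouse genes. The labels named no treatment and no second group, so the data were used to describe which genes and cell types the tissue expressed and where the replicates differed. Levels are given as the mean TPM ± SD over the replicates (n = 2), and ratios as log2 of replicate 2 over replicate 1 after TMM scaling. A gene list is called above or below the random lists, or inside the random range, by where its mean log2(TPM + 1) lay against the central 95% of random lists of expressed coding genes.

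Genes at 1 TPM or more numbered 15785 in both libraries, 14052 of them protein coding. The most abundant nuclear coding transcripts were those of the globin genes Hba-a2 at 10596 ± 1969 TPM and Hbb-bs at 5271 ± 1137 TPM, which red blood cells express, and Hbb-bt, another globin gene, stood at 3596 ± 660.1 TPM. The 20 most abundant also held genes of bone and connective tissue matrix, with the collagen gene Col1a1 at 3345 ± 13.2 TPM, the matrix glycoprotein gene Sparc at 2783 ± 112 TPM, Col3a1 at 2425 ± 264 TPM and Col1a2 at 1827 ± 49.8 TPM. Ftl1, a ferritin subunit, stood at 3731 ± 22.0 TPM, the ubiquitin gene Ubb at 2621 ± 83.6 TPM, the galectin gene Lgals1 at 2128 ± 82.3 TPM, Tmsb4x at 1946 ± 123 TPM and the chaperone gene Hspa8 at 1807 ± 33.8 TPM. Col1a1 lay on chromosome 11 from 94936224 to 94953042 and Hba-a2 on chromosome 11 from 32296489 to 32297298 in GRCm38. Values of Hba-a1 (3936 ± 814 TPM), Hba-a2, H3f3a (2009 ± 114 TPM) and the histone gene Hist1h2ap (2354 ± 117 TPM) are uncertain, because reads can be shared with near-identical copies. The same holds for other genes with such copies, Ppia among them.

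By summed TPM, nuclear protein coding genes other than globin, histone and ribosomal protein genes took 68.5 ± 0.635% of the transcripts (n = 2). Genes for ribosomal proteins took 6.11 ± 0.0544%, globin genes 2.37 ± 0.448% and replication-dependent histone genes 0.340 ± 0.0246%. The 7SL RNA genes Rn7s1 and Rn7s2, whose product is the RNA of the signal recognition particle, took 3.30 ± 0.429%, long noncoding RNA genes 2.58 ± 0.102% and other short noncoding RNA genes 0.593 ± 0.0141%. Most of that last share fell on Gm22133, chosen after its value was seen, a microRNA model inside Ftl1 at 3723 ± 172 TPM, whose reads cannot be separated from those of Ftl1 with certainty. Mitochondrial messenger RNA took 2.26 ± 0.180%, and mitochondrial rRNA and tRNA 0.385 ± 0.0903%. Pseudogenes took 5.07 ± 0.648%, a share that includes Gm28437, a nuclear copy of mitochondrial sequence at 7398 ± 570.3 TPM that was chosen after its value was seen. It also includes processed copies of coding genes, whose reads cannot be separated from those of the coding genes with certainty. Added spike-in RNA took 8.28 ± 2.62%. Short RNA weighs more in TPM than in counts, where the coding share was 87.0% and the spike-in share 3.75%.

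Of the bone, cartilage, osteoclast and tendon lists, only bone lay above the random lists. Bone genes were abundant, with 13 of 14 at 1 TPM or more in both libraries and a median of 60.9 ± 1.66 TPM, above the random lists, and were led by Col1a1, Sparc and Col1a2. All but 1 of the 18 cartilage genes were detected, with a median of 28.6 ± 10.6 TPM, inside the random range. The cartilage collagen genes Col2a1 and Col9a3 stood at 243 ± 87.3 TPM and 141 ± 42.9 TPM, and Cnmd, which encodes chondromodulin, at 87.8 ± 27.8 TPM. Osteoclast genes, of which 5 of 8 were detected, had a median of 2.69 ± 0.0742 TPM, below the random range, although Ctsk, the protease that degrades bone collagen, reached 104 ± 10.6 TPM, Mmp9 35.05 ± 1.98 TPM and the acid phosphatase gene Acp5 32.8 ± 4.18 TPM. Tendon genes, all 6 detected, had a median of 24.7 ± 0.704 TPM inside the random range, with Tnmd, a tendon membrane protein gene, at 46.9 ± 0.834 TPM, Thbs4 at 32.7 ± 12.0 TPM and Kera at 31.9 ± 1.07 TPM.

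All 24 skeletal muscle genes were detected, with a median of 127 ± 34.6 TPM, above the random lists. The sarcomeric actin genes Actc1 and Acta1 stood at 1038 ± 204 TPM and 917 ± 164 TPM, and the myosin light chain gene Myl1 at 546 ± 115 TPM. Genes listed for heart were mostly low, with 4 of 6 detected and a median of 2.40 ± 0.583 TPM, below the random range. Their 3 most abundant were Nkx2-5, a cardiac transcription factor gene, at 8.04 ± 1.56 TPM, Tnni3 at 4.49 ± 0.240 TPM and Myl2 at 3.30 ± 0.608 TPM.

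The epithelia of skin and mouth were well represented. Basal and simple epithelial genes, all 15 detected, had a median of 135 ± 28.6 TPM, with the basal keratin genes Krt14 at 946 ± 83.6 TPM, Krt15 at 931 ± 56.6 TPM and Krt5 at 738 ± 78.4 TPM. That median and its SD were those of Krt8, while the median ratio of the list between replicates was 1.04-fold. Suprabasal and cornified epidermis genes, 12 of 13 detected, had a median of 58.5 ± 6.53 TPM, with Krtdap at 1412 ± 109 TPM and the keratin genes of differentiating layers Krt1 at 608 ± 4.88 TPM and Krt10 at 337 ± 6.58 TPM. Both lists lay above the random lists. Hair placode genes, all 7 detected, had a median of 2.35 ± 0.0919 TPM below the random range, although Sostdc1, a secreted BMP and Wnt antagonist gene, reached 182 ± 8.59 TPM, Lhx2 14.6 ± 1.22 TPM and Wnt10b 4.70 ± 1.37 TPM.

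Genes listed as tooth regulators were mostly detected, and genes of enamel and dentin matrix hardly. The regulators are not particular to teeth, and Msx1, for example, is also in the cranial mesenchyme and palate lists. The tooth regulator list, 10 of 12 detected with a median of 6.93 ± 1.39 TPM, lay inside the random range and included the homeobox genes Msx1 at 152 ± 9.16 TPM and Lhx8 at 25.2 ± 1.57 TPM. Of the 8 enamel and dentin matrix genes only Ambn, which encodes ameloblastin, passed 1 TPM in both libraries, at 4.51 ± 0.255 TPM, and the median of 0.0550 ± 0.0283 TPM lay below the random range. The mean TPM was 0.935 for Odam, 0.140 for Klk4, 0.0600 for Amelx, 0.0450 for Amtn, 0.0250 for Enam and 0.0150 for Dspp. No count fell on Mmp20 in either library, where 1 read on a transcript of 1 kb made 0.0406 TPM in replicate 1 and 0.0389 TPM in replicate 2.

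Transcription factors of the facial mesenchyme were abundant while Hox genes, which pattern more posterior segments, were low. All 16 cranial mesenchyme factors were detected, with a median of 46.4 ± 1.80 TPM above the random lists. Msx1 led them, on chromosome 5 from 37820485 to 37824583 in GRCm38, followed by Osr2 at 109.8 ± 14.1 TPM and Prrx1 at 82.6 ± 5.06 TPM. Palate genes, 16 of 17 detected with a median of 22.4 ± 1.78 TPM, lay inside the random range, and besides Msx1 and Osr2 were led by the growth factor gene Tgfb3 at 55.2 ± 1.53 TPM. Of 39 Hox genes 6 passed 1 TPM in both libraries and the median was 0.0550 ± 0.0212 TPM, below the random range. These 6 were Hoxd8 (5.71 ± 0.969 TPM), Hoxc13 (3.64 ± 0.742 TPM), Hoxd9 (2.91 ± 0.969 TPM), Hoxd3 (1.81 ± 0.410 TPM), Hoxd1 (1.64 ± 0.495 TPM) and Hoxc5 (1.60 ± 0 TPM).

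Genes that pattern the pharyngeal arches spanned a wide range, with 12 of 14 detected and a median of 5.34 ± 0.788 TPM, below the random range. The endothelin receptor gene Ednra stood at 41.3 ± 4.91 TPM and its ligand gene Edn1 at 4.15 ± 0.0849 TPM. Among the homeobox genes of the Dlx family, Dlx5 stood at 40.5 ± 4.41 TPM, Dlx3 at 28.7 ± 1.03 TPM, Dlx1 at 8.79 ± 1.40 TPM, Dlx2 at 5.82 ± 1.17 TPM, Dlx4 at 4.86 ± 0.403 TPM and Dlx6 at 2.37 ± 0.346 TPM. Barx1 reached 14.5 ± 0.841 TPM, Gsc 11.2 ± 0.431 TPM, Pou3f3 3.33 ± 0.240 TPM and Hand2 2.59 ± 0.912 TPM. Hand1 and Nkx3-2, with 0.525 TPM and 0.220 TPM, were not detected by the threshold of 1 TPM.

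Neural genes were present at low to middle levels. Pan-neuronal genes, 10 of 11 detected, had a median of 7.10 ± 2.29 TPM, inside the random range, with the growth cone gene Gap43 at 90.4 ± 4.05 TPM, the neuronal tubulin gene Tubb3 at 36.2 ± 2.28 TPM and Stmn2 at 32.8 ± 0.205 TPM. Sensory neuron genes, 5 of 8 detected, had a median of 1.42 ± 0.117 TPM below the random range, with Isl1 at 15.5 ± 2.32 TPM and the intermediate filament gene Prph at 6.66 ± 0.488 TPM. Of 12 forebrain genes only Emx2, at 13.45 ± 1.27 TPM, was detected in both libraries, and the median of 0.335 ± 0.0141 TPM lay below the random range. Schwann cell genes, all 11 detected with a median of 8.73 ± 0.919 TPM inside the random range, were led by the myelin protein gene Pmp22 at 194 ± 3.74 TPM, Fabp7 at 26.5 ± 11.1 TPM and the neuregulin receptor gene Erbb3 at 19.8 ± 1.31 TPM. Melanocyte genes, 7 of 9 detected with a median of 3.96 ± 0.856 TPM below the random range, were led by the pigment genes Pmel at 22.4 ± 1.41 TPM and Dct at 18.7 ± 2.31 TPM and by Kit at 16.3 ± 0.438 TPM.

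Both sense organ lists lay below the random range. Olfactory epithelium genes, 10 of 11 detected with a median of 3.70 ± 0.297 TPM, were led by Ebf2 at 15.7 ± 2.17 TPM, the adenylate cyclase gene of odour transduction Adcy3 at 13.5 ± 0.290 TPM and Gng8 at 12.6 ± 1.34 TPM. Lens and retina genes, 10 of 20 detected, had a median of 1.83 ± 0.230 TPM, with the crystallin genes Cryab at 88.8 ± 16.04 TPM and Cryaa at 8.30 ± 2.18 TPM and the homeobox gene Otx2 at 6.59 ± 1.13 TPM. Cryab is also expressed in muscle.

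Blood, vessel and immune cell genes differed by lineage. Erythroid genes, 12 of 13 detected with a median of 50.2 ± 3.51 TPM, and mast cell genes, all 4 detected with a median of 170.3 ± 30.7 TPM, lay above the random lists. Mast cell proteases led the latter list, with the chymase gene Cma1 at 276 ± 34.7 TPM, Cpa3 at 181 ± 19.7 TPM and the tryptase gene Tpsb2 at 159.8 ± 41.7 TPM. Macrophage genes (all 13 detected, median 21.9 ± 0.820 TPM), endothelial genes (all 12, median 24.6 ± 0.0849 TPM) and pericyte and smooth muscle genes (all 9, median 13.6 ± 0.148 TPM) lay inside the random range. Their most abundant members were the lysozyme gene Lyz2 at 109.9 ± 8.07 TPM, Tyrobp at 78.4 ± 5.11 TPM and the complement gene C1qb at 68.4 ± 0.559 TPM for macrophages. For endothelium they were Egfl7 at 94.1 ± 9.77 TPM, Sox18 at 55.9 ± 6.55 TPM and Esam at 43.1 ± 2.99 TPM. For pericytes and smooth muscle they were the smooth muscle actin gene Acta2 at 292 ± 28.4 TPM, Pdgfrb at 47.5 ± 1.76 TPM and Tagln at 27.9 ± 2.16 TPM. Lymphocyte genes were mostly not detected, with only Lck passing 1 TPM among 10, at 4.88 ± 0.693 TPM, and a median of 0.178 ± 0.0106 TPM below the random range.

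Genes of glands and inner organs were low, and each such list lay below the random range. Adipocyte genes had the highest median among them, 1.295 ± 0.502 TPM with 4 of 8 detected, led by the fatty acid carrier gene Fabp4 at 24.8 ± 1.74 TPM, Cebpa at 13.0 ± 0.983 TPM and Pparg at 7.95 ± 1.00 TPM. Salivary gland genes had 1 of 8 detected and a median of 0.313 ± 0.237 TPM, with the water channel gene Aqp5 at 3.13 ± 1.45 TPM and Dcpp3 at 3.05 ± 3.18 TPM. Pituitary genes had 2 of 7 detected and a median of 0.390 ± 0.297 TPM, with the hormone precursor gene Pomc at 3.25 ± 2.01 TPM and Lhx3 at 1.23 ± 0.297 TPM. Liver genes had 2 of 10 detected and a median of 0.268 ± 0.180 TPM, with the albumin gene Alb at 2.25 ± 0.325 TPM, and lung genes had 2 of 4 detected and a median of 0.563 ± 0.0318 TPM, with the surfactant gene Sftpc at 1.27 ± 0.156 TPM. None of the 12 genes listed for gut, kidney and pancreas was detected, and their median was 0.02 ± 0.0141 TPM.

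Signalling genes of facial development were broadly detected, at medians inside the random range. All 8 Hedgehog genes were detected with a median of 15.4 ± 1.11 TPM. The signal transducer gene Smo stood at 42.0 ± 2.23 TPM, the receptor gene Ptch1 at 13.9 ± 2.37 TPM, and the decoy receptor gene Hhip at 15.3 ± 0.933 TPM. The effector genes Gli1, Gli2 and Gli3 stood at 11.7 ± 0.375, 15.5 ± 1.28 and 18.9 ± 1.18 TPM, and the ligand gene Shh at 2.12 ± 0.417 TPM. BMP pathway genes (11 of 12, median 22.3 ± 1.48 TPM) were led by the target genes Id3 at 347 ± 0.615 TPM, Id2 at 225 ± 2.86 TPM and Id1 at 120.1 ± 8.09 TPM. FGF pathway genes (13 of 14, median 13.3 ± 1.07 TPM) were led by the receptor genes Fgfr1 at 140.4 ± 2.90 TPM and Fgfr2 at 114 ± 1.73 TPM and by Dusp6 at 50.7 ± 0.205 TPM. Wnt pathway genes (15 of 16, median 15.4 ± 1.05 TPM) were led by the ligand gene Wnt5a at 128 ± 4.94 TPM, Dkk3 at 56.9 ± 2.63 TPM and Lef1 at 41.1 ± 2.78 TPM. Retinoic acid genes (all 10, median 22.4 ± 1.47 TPM) were led by the binding protein genes Crabp1 at 382 ± 15.4 TPM and Crabp2 at 161 ± 0.905 TPM and the receptor gene Rarg at 92.6 ± 4.51 TPM.

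Genes of proliferation and growth were abundant. All 18 cell cycle genes were detected with a median of 101 ± 1.48 TPM, led by Cdk1 at 285 ± 17.6 TPM, Birc5 at 184 ± 10.3 TPM and Pcna at 161 ± 9.14 TPM. All 19 imprinted genes were detected with a median of 184 ± 15.9 TPM, led by Mest at 1087 ± 51.3 TPM, the noncoding RNA gene Meg3 at 1079.9 ± 0.191 TPM and the cell cycle inhibitor gene Cdkn1c at 1003 ± 114 TPM. Housekeeping genes (all 10, median 762 ± 8.98 TPM) were led by Actb at 4292 ± 281 TPM, Eef1a1 at 4195 ± 242 TPM and Ppia at 3581 ± 0.120 TPM. The level of Ppia is uncertain beyond that SD, because the pseudogene Gm10123, at 100% identity to it, stood at 3184 ± 166 TPM. Ribosomal protein genes (93 of 98, median 557 ± 4.29 TPM) were led by Rpl41 at 3366 ± 82.8 TPM, Rps19 at 2398 ± 53.4 TPM and Rpl32 at 1698 ± 34.1 TPM. The 13 mitochondrial messenger RNA genes were all detected, with a median of 1068 ± 72.4 TPM and mt-Atp6, a subunit of ATP synthase, at 5957 ± 593 TPM. All of these lists lay above the random lists.

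Noncoding and stress lists varied. Non-polyadenylated RNA genes (5 of 6, median 188.5 ± 20.2 TPM) lay above the random lists, with Rn7s1 and Rn7s2 at 16502 ± 2147 and 16503 ± 2147 TPM, values these near-identical copies share. Rn7sk, an inhibitor of transcription elongation, stood at 287 ± 24.9 TPM, the RNase P RNA gene Rpph1 at 90.1 ± 15.6 TPM, Rmrp at 5.29 ± 0.488 TPM and the telomerase RNA gene Terc at 0.675 TPM. Nuclear long noncoding RNA genes (all 8, median 35.9 ± 0.548 TPM) lay above the random lists as well, with Malat1 at 5869 ± 364 TPM. Immediate early genes (10 of 11, median 22.1 ± 3.51 TPM) and hypoxia genes (all 10, median 55.8 ± 5.91 TPM) lay inside the random range, led by Jun at 78.4 ± 8.06 TPM and by the lactate dehydrogenase gene Ldha at 1218 ± 8.67 TPM. The 64 replication-dependent histone genes, 49 detected with a median of 4.13 ± 0.587 TPM, lay below it. The sex chromosome list (all 5, median 20.2 ± 2.25 TPM) lay inside it, with the X inactivation RNA gene Xist at 27.1 ± 1.06 TPM beside the Y genes Eif2s3y at 26.3 ± 2.70 TPM, Ddx3y at 20.2 ± 2.25 TPM, Uty at 8.33 ± 0.332 TPM and Kdm5d at 6.65 ± 1.16 TPM.

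In the test behind these statements, the mean log2(TPM + 1) of each of the 50 lists was compared with 10000 random lists of the same size drawn from coding genes at 1 TPM or more in either library. By that test 14 lists lay above the central 95% and 19 below it. The lists held 731 entries from 710 genes, and 577 entries were detected. Against random lists drawn from all coding genes, 22 lists lay above and 10 below, since that background holds silent genes. The plot of list medians shows both libraries beside each other. A list's median can move unlike its members. The erythroid median was 47.73 TPM in replicate 1 and 52.69 TPM in replicate 2, while 8 of 12 members were lower in replicate 2 after TMM scaling.

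**Figure D1:**
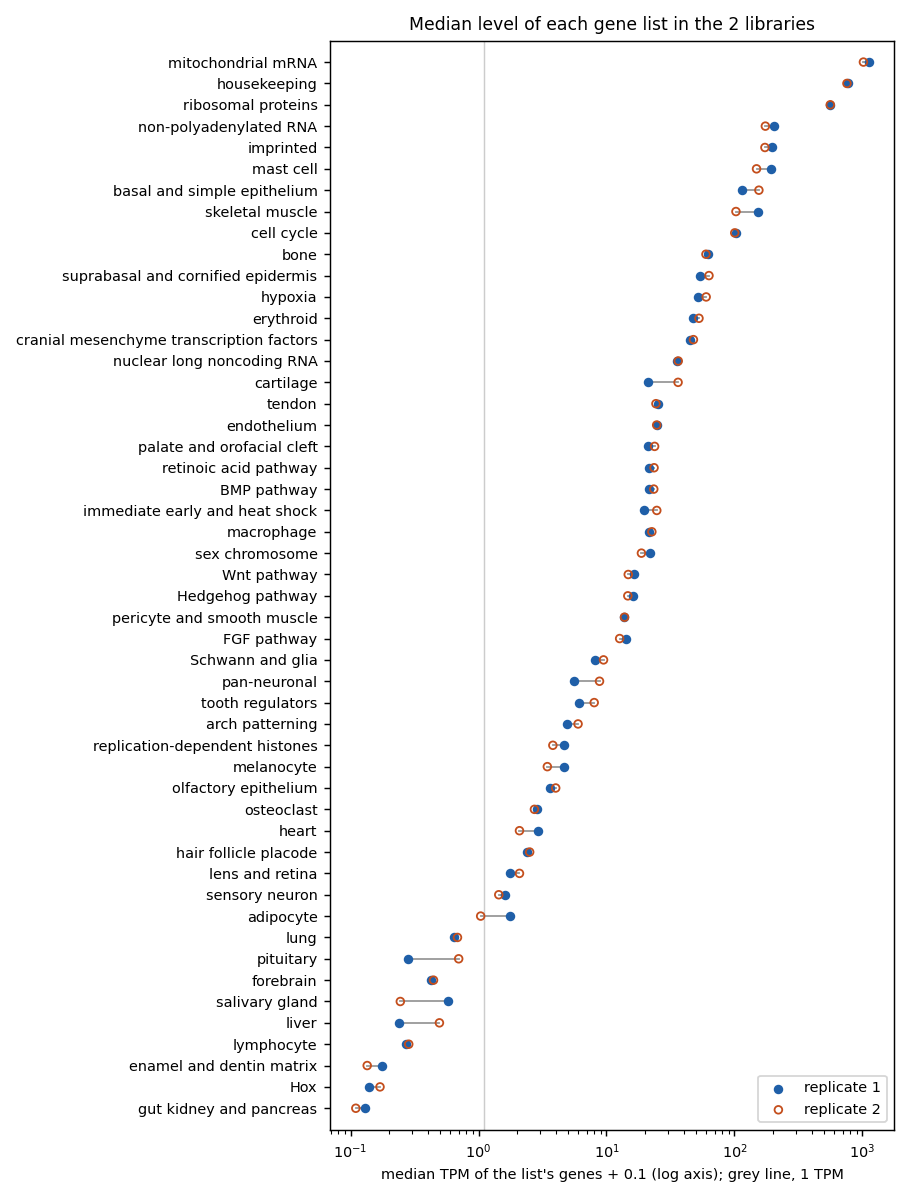
Median TPM of each gene list with 0.1 added (log axis; grey line, 1 TPM), with 1 point for each library (filled, replicate 1; open, replicate 2) and lists ordered by level. Mitochondrial, housekeeping and ribosomal protein genes sat highest, and genes of gut, kidney and pancreas lowest.

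Ratios between genes of a family were called in 23 of 24 fixed pairs. Among muscle genes, the embryonic myosin gene Myh3 exceeded the perinatal Myh8 by 2.71-fold (log2 1.44 ± 0.03, n = 2) and the slow Myh7 by 13.1-fold, while the fast troponin genes Tnnt3 and Tnni2 were 0.583-fold and 0.562-fold the level of the slow Tnnt1 and Tnni1. Myog, a regulator of muscle differentiation, exceeded Myf5, a regulator of myoblasts, by 11.0-fold. Adult globin exceeded embryonic globin, by 19.1-fold for Hbb-bs over Hbb-y (log2 4.25 ± 0.70) and 1166-fold for Hbb-bt over Hbb-bh1. Col2a1 exceeded the hypertrophic cartilage gene Col10a1 by 402-fold (log2 8.65 ± 0.89), and Col1a1 exceeded Bglap, the osteocalcin gene of mature osteoblasts, by 163-fold. Krt14 exceeded Krt10 by 2.80-fold and the simple epithelial keratin gene Krt8 by 7.08-fold. Krt5 exceeded Krt1 by 1.21-fold, a small difference that varied between replicates (log2 0.28 ± 0.17).

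Dlx5 exceeded Dlx1 by 4.58-fold and its genomic neighbour Dlx6 by 16.5-fold, and Dlx1 exceeded Dlx2 by 1.51-fold. Alx4 and Dlx5 exceeded Hoxa2 by 28.4-fold and 98.02-fold, and Msx1 exceeded Hoxa3, which had 5 and 7 counts, by 799.8-fold (log2 9.64 ± 0.02). Bmp4 exceeded Bmp2 by 1.69-fold, Wnt5a exceeded Wnt3 by 18.2-fold, Fgfr1 exceeded Fgfr2 by 1.23-fold, Gli3 exceeded Gli1 by 1.60-fold and Pax9 exceeded the eye and nose gene Pax6 by 3.75-fold. The ratio of the osteoblast factor genes Sp7 and Runx2, 1.20-fold, was not called. A pair was called when the deposited credibility intervals of its genes did not overlap in either library and the direction was the same in both. The call did not weigh the spread between replicates. An interval need not hold the TPM it belongs to. In replicate 1, for example, Hba-a2 stood at 11987.9 TPM with bounds of 11634.7 and 11790.5 TPM. For genes near 0 the fold also rested on the pseudocount of 0.1 TPM. With a pseudocount of 1 TPM it was 159-fold for Col2a1 over Col10a1, 9.60-fold for Alx4 and 31.5-fold for Dlx5 over Hoxa2, and 140.1-fold for Msx1 over Hoxa3. Ratios between genes also depend on transcript models and on effective length, which the intervals do not cover.

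Transcript models were compared within genes. Pkm-201 took 90.01 ± 1.00% of the transcripts of the pyruvate kinase gene Pkm (n = 2), Msx1-201 took 95.6 ± 0.191% of Msx1, and Tgfb3 had 1 model. In skeletal genes, Col2a1-202 took 81.3 ± 0.0880% of Col2a1, Col11a2-201 took 73.8 ± 2.997% of Col11a2, Postn-203 took 59.8 ± 0.257% of Postn and Runx2-202 took 25.0 ± 1.90% of Runx2. In receptor and adhesion genes, the leading models were Fgfr1-202 (41.7 ± 3.44%), Fgfr2-217 (27.2 ± 0.253%), Fgfr3-211 (42.3 ± 2.30%), Cd44-207 (50.1 ± 1.28%) and Fn1-201 (40.7 ± 3.41%). In muscle and regulator genes they were Tnnt3-215 (24.5 ± 1.41%), Tnnt1-201 (30.5 ± 0.539%), Tpm2-203 (48.3 ± 0.734%), Mef2c-203 (52.6 ± 2.99%), Mef2d-201 (46.7 ± 0.978%) and Numb-204 (53.9 ± 2.28%), and Eda-206 took 66.0 ± 7.75% of Eda. The leading model was the same in both libraries for 20 of the 22 genes fixed for this comparison, and differed for Tpm1 and for Trp63, where Trp63-205 took 33.4 ± 2.06% and Trp63-201 took 29.4 ± 3.81%. Among 6954 genes at 10 TPM or more with more than 1 model, the leading model differed in 430 (6.18%). Shares rest on how reads common to several models were divided.

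The replicates were alike for most genes. Pearson's r of log2(TPM + 1) was 0.993 across 43346 genes, which are not independent replicates, and Spearman's rho of TPM was 0.953. Among 18318 genes with 10 or more counts in both libraries, the median absolute log2 ratio was 0.12 and 90.9% lay within 1.5-fold. The spread fell with depth, from 0.35 for genes of 10 to 100 counts to 0.06 for genes of 10000 counts or more. The biological coefficient of variation was 12.6%, and the chi-square of counts over genes was 13.4 per degree of freedom. That chi-square covers counting error only, with reads taken as independent, and served to check that the libraries were not repeat counts of 1 library.

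All 61 spike-in RNAs with 10 or more counts were higher in replicate 2, by 1.58-fold in sum (log2 0.66, SD between spike-ins 0.17). Scaling to spike-in totals therefore moved the median log2 ratio of all genes by −0.65, against 0.00 with TMM, and ratios are given relative to that median. With 2 replicates of 1 group no p-value was computed, since the smallest p an exact two-sided sign test could give was 0.5.

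Among the 45 lists tested here, skeletal muscle had the lowest and cartilage the highest median ratio. Skeletal muscle genes were lower in replicate 2 in 23 of 24 cases, with a median log2 ratio of −0.43 (0.745-fold). Actc1 stood at −0.40, Acta1 at −0.37 and Myl1 at −0.42. Cartilage genes were higher in replicate 2 in 16 of 18 cases, with a median of 0.58 (1.49-fold). Col2a1 stood at 0.75, Col9a3 at 0.62 and Cnmd at 0.69, and Matn1, a cartilage matrix gene chosen after its value was seen, at 1.42. No random list was as low as the muscle list or as high as the cartilage list. On the raw spike-in scale the median of cartilage genes was −0.07 and that of muscle genes −1.08. Every list named as higher in replicate 2 turned negative there. Places among random lists stayed, since a change of scale moves list members and random genes nearly alike.

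The other 6 lists higher in replicate 2 shifted less. Olfactory epithelium genes had a median of 0.35 (0.23 at a minimum of 100 counts) with 10 of 11 higher, and Ebf2 stood at 0.23, Adcy3 at 0.02 and Gng8 at 0.22. Cranial mesenchyme factors had a median of 0.18 with 12 of 16 higher, including Msx1 at 0.12, Osr2 at 0.26 and Prrx1 at 0.20. Retinoic acid genes (0.13, 9 of 10), hypoxia genes (0.11, 7 of 10) and BMP pathway genes (0.11, 9 of 12) followed, although Crabp1 at −0.08 and Id3 at 0.00 did not share the direction. Basal and simple epithelium genes had a median of 0.06 (0.09 with library totals) with 9 of 15 higher, which joined the simple keratin gene Krt8 at 0.44 to the basal genes Krt14 at −0.18, Krt15 at −0.11 and Krt5 at −0.22. At a minimum of 100 counts the hypoxia and BMP lists came inside the random range.

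Another 12 lists were lower in replicate 2. Erythroid genes had a median of −0.25 with 8 of 12 lower, while their mean was −0.04, and Hba-a2 stood at −0.38 and Hbb-bs at −0.42. Mast cell genes were lower in 4 of 4 cases with a median of −0.30, including Cma1 at −0.26, Cpa3 at −0.22 and Tpsb2 at −0.54. Imprinted genes were lower in 18 of 19 cases (−0.19), including Cdkn1c at −0.23 and Mest at −0.09. Melanocyte genes (−0.26, 6 of 8), Hox genes (−0.37, 8 of 12) and heart genes (−0.39, 4 of 5) were lower as well, though Hox genes by −0.12 with ratios of TPM, and heart genes had too few members for a minimum of 100 counts. Osteoclast genes (−0.17, 5 of 8) and pericyte and smooth muscle genes (−0.11, 5 of 9) were lower by less, and the osteoclast list came inside the random range at a minimum of 100 counts or with matching on length. Mitochondrial messenger RNA (−0.17, 12 of 13), non-polyadenylated RNA (−0.27, 5 of 5), nuclear long noncoding RNA (−0.11, 6 of 8) and replication-dependent histone genes (−0.17, 37 of 51) completed the set. The histone genes had reads shared among copies and a median of −0.10 at a minimum of 100 counts. Rn7s1 and Rn7s2, both in the non-polyadenylated list, shared reads as well.

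Each of 45 lists was compared with 10000 random lists matched on expression, and 20 lay outside the central 95% of these where chance would give 2.25. The lists inside were bone (0.01, with a mean of −0.07), tendon (−0.07), tooth regulators (0.11), suprabasal epidermis (0.03, with a mean of −0.03), hair placode (0.07), arch patterning (0.11), palate (0.06), pan-neuronal (0.11), sensory neuron (0.14), forebrain (0.06), lens and retina (0.20) and Schwann cell genes (0.07). So were those of endothelium (−0.08), macrophages (−0.05), lymphocytes (0.22), adipocytes (−0.21), salivary glands (0.14, with a mean of −0.29), cell cycle (−0.02), immediate early (0.09) and sex chromosome genes (−0.04). The Hedgehog (−0.07), FGF (0.00), Wnt (−0.04, with a mean of 0.04), housekeeping (−0.01) and ribosomal protein (−0.02) lists were inside as well. Enamel and dentin matrix, pituitary, liver, lung, and gut, kidney and pancreas genes had fewer than 3 members at 10 counts in both libraries and were not tested. Members of a list are not independent, and some lists share members, as the imprinted and nuclear long noncoding RNA lists do. The random lists held coding genes only, and the comparison is between a pair of pools, not between conditions.

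**Figure D2:**
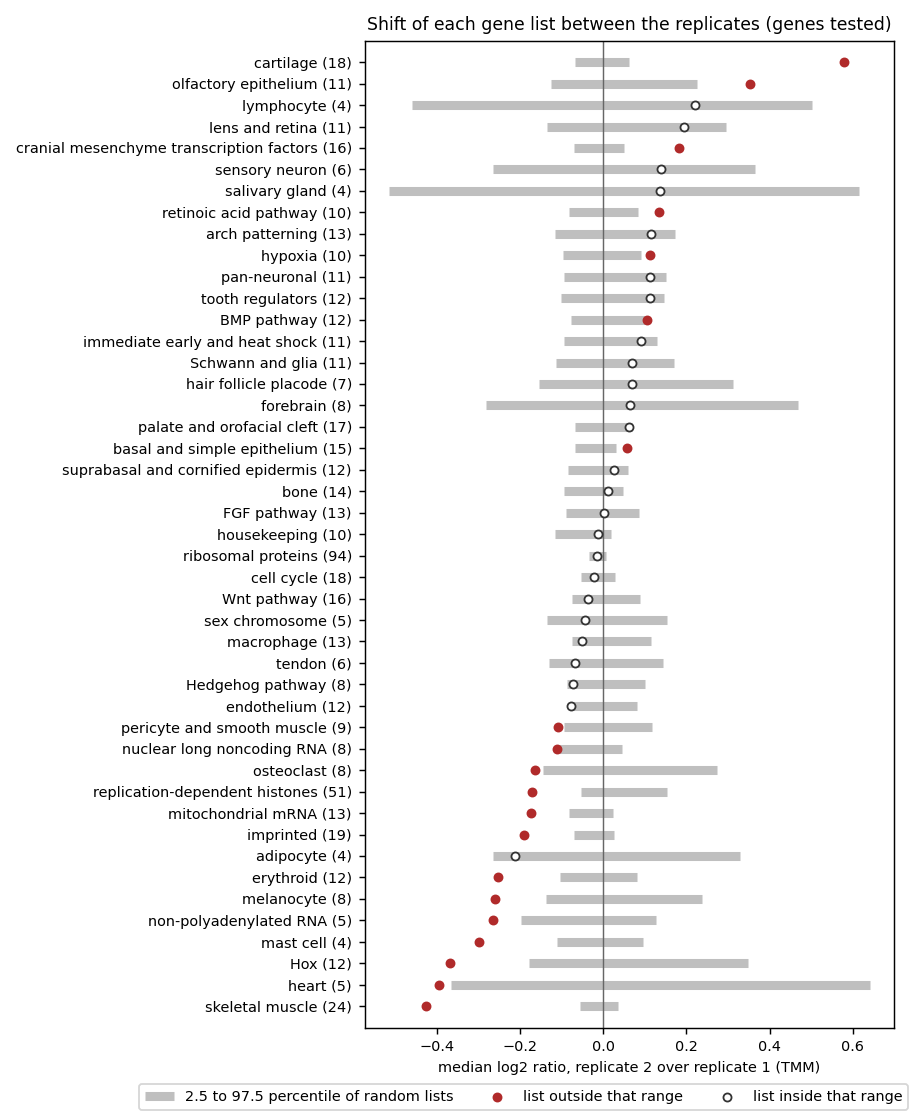
Median log2 ratio of replicate 2 to replicate 1 for each gene list after TMM scaling (points), with the central 95% of random lists matched on expression (bars) and red points outside it. Cartilage genes sat highest at 0.58 and skeletal muscle genes lowest at −0.43; on the spike-in scale all values move down by 0.65 and those of the higher lists turn negative.

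Single genes over 2-fold were few. Of 14414 genes with 100 or more counts in the library with more counts, 94 were at least 2-fold higher and 189 at least 2-fold lower in replicate 2, together 1.96%. Pseudogenes made up 137 of those lower and 2 of those higher, whereas among 13548 coding genes 86 were higher and 45 lower. With a minimum of 10 counts the numbers were 510 higher and 762 lower, and with ratios of TPM 46 were higher.

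The coding gene with the largest ratio was Oc90 (ENSMUSG00000015001.13), which encodes a protein of the inner ear's otoconia, on chromosome 15 from 65876053 to 65912397 in GRCm38. It had 1 count in replicate 1 and 925 in replicate 2, a ratio of 300.6-fold (log2 8.23) that rests on the prior count of 2. The 95% counting interval, from 7.31 to 15.10 on the log2 scale, was computed without a prior count. Late cornified envelope genes of the outermost skin followed, within chromosome 3 from 92925287 to 92968281, with log2 ratios of 2.15 for Lce3b (interval 1.79 to 2.58), 1.84 for Lce3c, 1.61 for Lce3e and 1.56 for Lce3a. Kprp, another cornified layer gene on chromosome 3, stood at 1.76, the histidine ammonia lyase gene Hal at 2.09, Otor at 1.94, 4833427G06Rik at 1.70 and the chemokine gene Cxcl13 at 1.61.

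The hair keratin-associated protein genes Krtap7-1 and Krtap8-1, on chromosome 16 between 89487379 and 89508323, were lower in replicate 2, at −1.91 (95% interval −2.59 to −1.41) and −1.71 (−2.09 to −1.38). Whether reads of the others among the 10 lowest were shared with copies elsewhere was not tested, so their ratios are uncertain. Gm10273 had 141 counts in replicate 1 and 0 in replicate 2, which a floor of 3 counts per library makes 49.0-fold lower. That is no lower bound, because its deposited credibility intervals overlapped, at 1.14 to 13.4 TPM in replicate 1 and 1.51e-05 to 5.12 TPM in replicate 2. The intervals of Duxbl3 overlapped as well, at 1.17 to 3.64 TPM and 0.890 to 2.86 TPM, the latter above its 0.68 TPM in replicate 2. Log2 ratios were −3.41 for Gm6619, −3.16 for Duxbl3, −2.62 for Gm6169, −2.08 for Gm12355, −1.98 for Psme2b, −1.90 for Adnp and −1.81 for Gm10184. Intervals and floors cover counting error only, and the strand that was counted is not given in the sources used here, so overlapping genes on opposite strands are not separated with certainty.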

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

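The test of the numbered sequences was planned, in that any signal outside the main measurement was to be listed, and no test here was chosen after its result was seen. The 26248 sequences that carry a bare number in place of a gene identifier, and that no comparison used, took an expected count of 42 in replicate 1 and 63.38 in replicate 2, above the 3 counts that a count of 0 allows. Of them 63 were long enough to be counted and 11 had counts, led by number 11364 with 35 and 50 counts at a length of 255 nucleotides. What these sequences are is not given in the sources used here, and no explanation, technical or biological, was tested.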

How the results depend on the processing

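The alternatives without pseudogenes, for further gene lists and, for these, with 10 counts in both libraries were chosen after seeing the data, and all other alternatives were planned. Of the main results 179 values kept their call or stayed near the main value, 16 moved and 4 no longer passed. No call reversed, where calls of lists rest on their place among random lists. Some of the 179 could hardly change, namely list calls under another size factor and class shares without 1 replicate. With spike-in totals the raw median of all 7 higher lists turned negative, from 0.58 to −0.07 for cartilage, since all genes shifted by −0.65. The 20 lists apart between replicates were the same 20 with DESeq2 size factors, library totals and spike-in totals. That outcome was nearly fixed in advance, since another size factor shifts list members and random genes nearly alike. TPM ratios gave 24 lists (20 shared), a minimum of 100 counts 17 (16 shared) and matching on length 21 (19 shared). At 100 counts osteoclast genes moved to −0.0434, hypoxia genes to 0.0818 and BMP genes to 0.0724, inside the random range, and with length matching osteoclast genes, at −0.17, lay inside it too. Heart genes had fewer than 3 members at 100 counts and gave no value. Apart from spike-in totals, lists that kept their call with a median over 1.5 times larger or smaller were Hox (−0.12, ratios of TPM), olfactory epithelium (0.23) and histones (−0.10) at 100 counts, basal and simple epithelium (0.09, library totals) and, of the further lists, keratin-associated proteins (−1.01 at 100 counts) and olfactory receptors (0.27, ratios of TPM). The cause was not tested.

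Genes over 2-fold numbered 510 higher and 762 lower at a minimum of 10 counts and 1075 and 1778 with none, since low counts scatter more. Ratios of TPM with a pseudocount of 1 gave 46 higher, and the cause was not tested. Coding genes only gave 45 lower and leaving out pseudogenes 52, since pseudogenes made up 137 of the 189 lower genes. Spike-in totals raised the replicate spread to 0.65 and the coefficient of variation to 0.348 (as a fraction), since all genes shifted together, and no minimum raised the spread to 0.20. Spearman's rho was 0.953. Summed counts gave a coding share of 87.0% and a spike-in share of 3.75%, since counts weigh long transcripts more. Random lists from all coding genes left 22 lists above and 10 below. At 50 TPM or more, 87 genes differed in their leading isoform, since fewer genes were tested.

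Without either replicate, detected genes numbered 16377 to 16399, called pairs 23, lists above the random range 14 to 15 and below it 19. No replicate can be left out of a ratio between them. Of other values 1318 were the same, many of them by construction. Levels and shares counted as the same within the SD of the 2 replicates. Leaving out 1 replicate cannot exceed that SD, so those values could not move and say nothing of robustness. Another 385 moved, mostly levels given as FPKM, which is another scale by construction. Only 1 no longer passed, olfactory receptors with 10 counts in both libraries (0.23), and 7 came to pass. These 7 were, with ratios of TPM, tooth regulators 0.12, palate 0.12, endothelium −0.11 and Hedgehog −0.12, at 100 counts lens and retina 0.24, and with length matching endothelium −0.08 and adipocyte −0.21. No paired analysis was possible because there was 1 group. Depth limits genes under 100 counts, where the spread between replicates was 0.35.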

Other observations

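All gene groups in this part were chosen after seeing the data, as were the tests of length, muscle share, nasal tissue, age, parent genes, inner ear and transcript models, and only the comparison of near-identical with diverged pseudogenes was set before its result was seen.

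Hair and outer skin genes moved in opposite directions between the replicates. Hair keratin genes, which build the hair shaft and its inner root sheath, were lower in replicate 2 in 16 of 18 cases, with a median log2 ratio of −1.01 relative to all genes, including Krt71 at −0.99 and Krt25 at −1.48. Keratin-associated protein genes, which encode proteins of the hair matrix, were lower in 33 of 38 tested cases with a median of −0.65, or −1.01 at a minimum of 100 counts. Late cornified envelope genes, of the outermost skin layer, were higher in 20 of 21 cases with a median of 1.17, including Lce3f at 0.82, and on the spike-in scale, where all genes sit at −0.65, they stayed above 0. Embryonic globin genes were higher in 3 of 3 cases (median 0.62, or 0.00 on the raw spike-in scale) and adult globin genes lower in 4 of 4 (median −0.40), with Hbb-y at 0.55 and Hba-x at 0.72. All 5 groups lay outside their random ranges, but this is no independent evidence. The hair and skin groups hold genes already named as extremes (Krtap7-1, Krtap8-1, Lce3a, Lce3b, Lce3c and Lce3e), and all 3 embryonic and 4 adult globin genes are in the erythroid list fixed earlier.

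Genes of nasal epithelium were higher in replicate 2. Motile cilia genes were higher in 24 of 24 cases with a median of 0.64, and regulators of ciliated cells in 6 of 6 with a median of 1.25, including Foxj1 at 1.16 and Mcidas at 1.28. Nasal secretory genes were higher in 9 of 11 cases with a median of 0.61, led by Bpifa1, a secreted airway protein gene, at 168 TPM in replicate 1 and 457 TPM in replicate 2. Olfactory sustentacular genes were higher in 8 of 8 cases (0.67), with Cbr2 at 204 ± 65.9 TPM (SD, n = 2). Olfactory receptor genes were apart when 10 counts in either library were enough, with a median of 0.87, or 0.27 with ratios of TPM, but with 10 counts in both their median of 0.23 lay inside the random range. On the raw spike-in scale the nasal secretory median was −0.03, while its place among random lists stayed the same, which a change of scale hardly affects. Of the nasal secretory genes 3 are also in lists fixed earlier.

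For the lower muscle and higher cartilage genes in replicate 2, gene length bias is argued against, because with random lists matched on length the muscle list stayed at percentile 0 and the cartilage list at percentile 100. More nasal tissue in the pool of replicate 2 stays open, because the motile cilia genes at percentile 100 were listed after nasal genes had been seen to differ and say nothing of muscle or cartilage. A smaller share of muscle stays open as well. Of the muscle genes 23 of 24 were lower, and their ratios had an SD of 0.225, at percentile 72.35 of random lists. That SD measures scatter about the list's own mean. A shift common to all muscle genes would leave it unchanged, so it cannot decide. The cartilage ratios had an SD of 0.419, at percentile 98.4. Younger embryos stay open too, because the suprabasal and cornified list lay at percentile 87.45. The globins and the hair keratin and keratin-associated protein genes would go with that, and the late cornified envelope genes would not. The osteoblast gene Bglap (−0.96) would go with it, but it was the lowest member of the bone list. That list had a median of 0.01 with 8 of 14 genes higher in replicate 2. Beyond age and the tissue make-up of the pools no biological explanation was tested, since the design has 1 group.

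Processed pseudogenes were lower in replicate 2, in 225 of 239 cases at 100 or more counts, with a median of −1.03. A fall of the coding genes they copy is argued against, because the 201 parent genes had a median of 0.00, which was 1.03 above that of the pseudogenes (SD of parents 0.173). A candidate explanation is that reads of coding genes were counted at near-identical copies in different shares, for example through read length or error rate. At 10 or more counts, copies at 98% identity or more lay −0.60 from those under 95% or unmatched, past the −0.27 of shuffled groups, but at 100 or more counts the difference of −0.89 rested on 5 diverged copies and did not pass. Copies between these bounds had the lowest median at 10 counts, −1.25, so identity alone does not order them, read properties stay open, and no biological explanation was tested.

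Oc90 had 1 count in replicate 1 and 925 in replicate 2. Reads piled on a short transcript model are argued against, because the models below the median length took 2.80% of its counts, and of its neighbours Efr3a, on the other strand, was at 0.10 and Hhla1 had 0 and 4 counts. Inner ear tissue in the pool of replicate 2 may be a source, but the other inner ear genes lay at percentile 75.71 with a median of 0.21 and 8 of 12 higher, from Kcne1 at −1.64 to Otor at 1.94, which leaves it open. Beyond inner ear tissue no biological explanation was tested.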
